A study of Mus musculus with 12 samples.

How the data were processed

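Poly(A) RNA of 12 hearts of male mice was sequenced, 3 in each of 4 groups: wild-type C57BL/6J (WT) or Cd163 knockout (KO) animals after sham surgery or after transverse aortic constriction (TAC). Per the labels' protocols, mice were 8 weeks old at surgery, the aorta was tied over a 27-gauge needle, RNA was extracted with TRIzol, mRNA was selected with oligo(dT) beads, and libraries were read as 150 bp pairs on an MGISEQ-T7. HISAT2 is the aligner named in the submitters' processing notes, with no version. The counting program, the genome build, the annotation, strand use in counting, the time between surgery and tissue collection, and the hour of collection are not given in the sources used here. The replicate numbers are those of the sample titles, which run 1, 2, 3 in the sham groups and 1, 3, 5 in the TAC groups. The labels list the libraries as separate samples without naming the animal of each, so p-values measure the spread between these samples.

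The deposited table holds whole-number read counts per gene for the 12 samples, not normalized, and its columns carry the sample titles. It lists 55357 Ensembl gene identifiers and no symbols. Symbols came from a mouse reference annotation whose build may not be that of the authors, and 52081 identifiers matched it. The 3276 unmatched identifiers stayed in the tests under their identifiers. No count was recorded in any library for 23267 identifiers. Total counts ran from 14150109 to 22602225 per library. Intervals and floors below cover counting error only, since the reads carry no molecular identifiers. A floor is 3 counts, summed over the group's libraries.

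Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr minimum by group, a robust quasi-likelihood fit of the 12 libraries with a coefficient per group and 8 residual degrees of freedom, and Benjamini-Hochberg adjustment with a threshold of 0.05. This left 15804 genes, which hold 99.9% or more of the counts of each library after rounding. There were 5 comparisons: TAC against sham in WT, TAC against sham in KO, KO against WT after sham, KO against WT after TAC, and the interaction, which is the TAC effect in KO minus that in WT. Values are TMM-scaled CPM as mean ± SD of n = 3 libraries, and log2 fold changes with ± SE. A gene said to stand at a value, or to rise or fall by a value, is given on the log2 scale unless CPM is named. Every adjusted p of a gene is from this edgeR test unless another tool is named.

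Before the data were examined, 37 gene lists were fixed for heart muscle, matrix, metabolism, immune cells, other cell types of the heart and of neighbouring organs, stress pathways and the circadian clock. Each list was set against the other tested genes with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. The lung and liver lists had under 3 tested members, so 35 lists were tested. Camera was repeated with an estimated correlation, and fry was run as a further alternative. Members past the gene test are counted after adjustment over all genes and adjusted over the list alone.

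The rule for genes to name was also fixed beforehand. It takes Cd163 and Il10. It takes up to 8 called genes per direction with the largest change among those with no overlap between the libraries of the groups, a mean of at least 1 CPM in a group and a symbol that is not a provisional name. It takes the 4 members of each list with the smallest p, of which some may be left out, and 1 such gene is not reported here. Where no gene passed, and for the interaction, it takes the 4 genes with the smallest p. Which lists are described with their genes was chosen after the list results were seen.

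The procedure was tested on simulated counts for the TAC comparison in WT, with 200 of 15804 genes changed. With the spread of the 12 libraries it recovered 31% of 2-fold and 72% of 4-fold changes, with 8 false calls, 7.2% of its calls. With the spread estimated without KO sham replicate 1 and WT TAC replicate 1 it recovered 76% and 92%, with 7 false calls, 4% of its calls. Genes were drawn independently, with the same spread in each group. These rates therefore do not cover a library that shifts many genes together. No pair of replicates agreed within counting noise, the closest pair differing by 2.15 times the Poisson variance. This argues against copied libraries and cannot tell whether 2 libraries came from 1 heart. Each library was counted as 1 sample.

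The alternatives were DESeq2 size factors in edgeR, library totals without TMM, DESeq2 1.42.0, limma-voom with sample weights, a fit that was not robust, no filter on low counts, and a filter at a mean of 1 CPM. Further alternatives were a block for the replicate number, a fit of only the compared groups, a minimum change of 2-fold and each library left out in turn. Leaving out KO sham replicate 1 and WT TAC replicate 1 together was added after the data were seen. Scaling by library totals in place of TMM moves the median log2 fold change by 0.15 for TAC in WT, −0.17 for TAC in KO, 0.11 for genotype after sham, −0.22 for genotype after TAC and −0.32 for the interaction, and changes are given relative to the TMM scale.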

Results

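Gene expression was measured by mRNA sequencing in 12 mouse hearts, to ask how loss of Cd163, the haemoglobin scavenger receptor of tissue macrophages, bears on the heart's response to pressure overload and on interleukin-10. There were 3 libraries each of WT sham, WT TAC, KO sham and KO TAC hearts. Total counts ran from 19987174 to 22400473 in WT sham, from 16671952 to 18608925 in WT TAC, from 15804176 to 22602225 in KO sham and from 14150109 to 16913259 in KO TAC libraries.

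The KO TAC hearts stood apart from all other groups, and 1 sham heart stood with them. On the first principal component, with 66.7% of the variance of the 1000 most variable genes, the KO TAC libraries lay between 40.4 and 44.9, and KO sham replicate 1 lay at 44.6. The other KO sham, the WT sham and 2 WT TAC libraries lay between −32.9 and −17.9, and WT TAC replicate 1 at 6.69. Rank correlations of KO sham replicate 1 were 0.985 to 0.990 with KO TAC libraries, against 0.927 to 0.935 with the other KO sham libraries. Those of WT TAC replicate 1 were 0.966 to 0.971 with KO TAC and 0.967 to 0.968 with the other WT TAC libraries. Transcripts of the mitochondrial genome made up 44.0 to 51.3% of the counts in KO TAC and 51.0% in KO sham replicate 1, against 24.8 to 36.9% in the other 8 libraries.

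**Figure D1:**
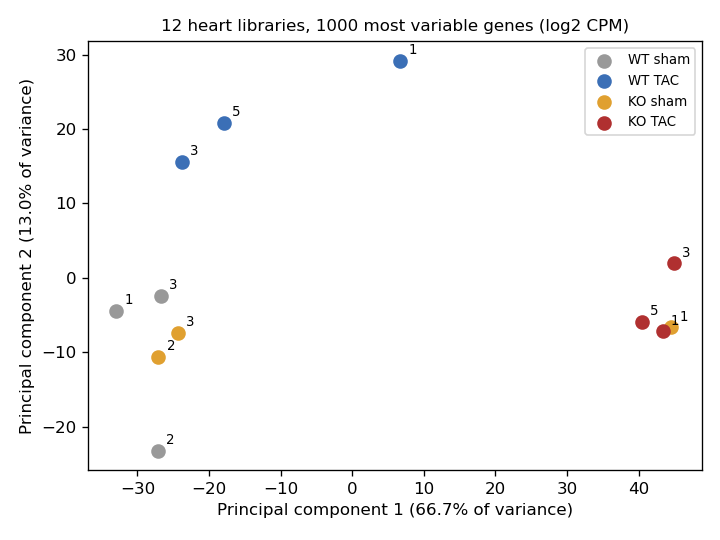
Principal components 1 and 2 of log2 CPM for the 12 libraries, 1 point per library, coloured by group and numbered by replicate. The 3 KO TAC libraries and KO sham replicate 1 lie between 40.4 and 44.9 on component 1, WT TAC replicate 1 at 6.69 and the others between −32.9 and −17.9.

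Cd163 (ENSMUSG00000008845) was lower in every KO library than in every WT library. Its raw counts were 255 to 592 in WT and 46 to 112 in KO libraries, so transcripts of the targeted gene were reduced and still counted; which part of the gene was deleted is not given in the sources used here. After TAC, Cd163 fell 6.43-fold in KO against WT, from 24.1 ± 8.99 to 3.74 ± 0.302 CPM (SD, n = 3 per group), with a log2 fold change of −2.69 ± 0.28 and an edgeR adjusted p of 0.00453. After sham the log2 fold change was −1.89 ± 0.27, from 15.2 ± 1.08 to 4.08 ± 0.816 CPM, and did not pass (adjusted p = 0.0748). It passed without KO sham replicate 1 (adjusted p = 0.0348) or WT TAC replicate 3 (0.00387), without the low-count filter (3.2e-06), in DESeq2 (7.42e-07) and in limma-voom (0.00017). TAC left Cd163 at 0.66 ± 0.25 on the log2 scale in WT (adjusted p = 0.245) and −0.14 ± 0.28 in KO (adjusted p = 0.748). Il10 (ENSMUSG00000016529), the anti-inflammatory cytokine named in the series title, had 2 counts over the WT sham, 1 over the WT TAC, 2 over the KO sham and 3 over the KO TAC libraries. These are at or under the floor of 3 counts, so no difference in Il10 was detectable at this depth.

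In WT hearts, 4 genes rose and 1 fell after TAC, the model of pressure overload. Tnc (ENSMUSG00000028364), the matrix protein tenascin C, rose 14.2-fold, from 0.929 ± 0.117 to 13.4 ± 7.51 CPM. Acta1 (ENSMUSG00000031972), the skeletal alpha-actin of the fetal heart programme, rose 9.66-fold, from 182 ± 57.2 to 1755 ± 702 CPM. The metal-binding metallothionein Mt1 (ENSMUSG00000031765) rose 5.40-fold and Ptgds (ENSMUSG00000015090), a prostaglandin D synthase, 4.55-fold, from 107 ± 8.19 to 488 ± 63.7 CPM. Enpp2 (ENSMUSG00000022425), the autotaxin that makes lysophosphatidic acid, fell 2.70-fold, from 12.5 ± 2.15 to 4.61 ± 0.207 CPM (SD, n = 3).

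These 5 genes, 4 higher and 1 lower, were all that edgeR called for TAC in WT. The log2 fold changes were 3.83 ± 0.53 for Tnc, 3.27 ± 0.42 for Acta1, 2.43 ± 0.31 for Mt1, 2.19 ± 0.19 for Ptgds and −1.43 ± 0.18 for Enpp2. The adjusted p lay between 0.00139 for Ptgds and 0.0360 for Tnc. At an unadjusted p under 0.05 there were 2562 genes. DESeq2 called 515, limma-voom 1030, edgeR without the low-count filter 137, with library totals 44 and on the 6 WT libraries alone 89. The count was 1 without WT sham replicate 1, 2 or 3, 2 without KO TAC replicate 1 or 3, and 3 without WT TAC replicate 5. It was 8 without WT TAC replicate 3 or KO sham replicate 2, 22 without WT TAC replicate 1 and 1058 without KO sham replicate 1, 550 higher and 508 lower. KO sham replicate 1 is in neither WT group and bears on this count through the spread shared by the fit and the genes tested. Ptgds passed with each library left out. Tnc, Acta1, Mt1 and Enpp2 did not pass without WT sham replicate 1, 2 or 3 or WT TAC replicate 5. Tnc, Acta1 and Mt1 did not pass without KO TAC replicate 1 or 3, Tnc and Enpp2 without WT TAC replicate 3 and Tnc without KO TAC replicate 5. The highest of these adjusted p was 0.332, for Tnc without WT sham replicate 2.

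**Figure D2:**
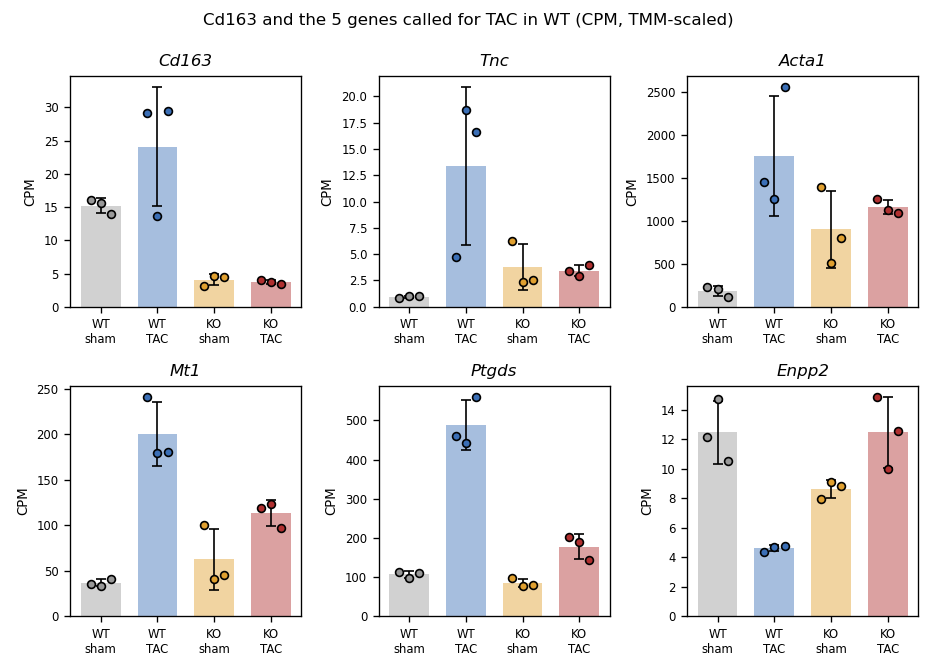
CPM of Cd163 and of the 5 genes called for TAC in WT, in the 4 groups; bars are means, whiskers SD and points the 3 libraries of a group. Tnc, Acta1, Mt1 and Ptgds are higher and Enpp2 is lower in each WT TAC than in each WT sham library, and Cd163 is lower in each KO than in each WT library.

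Around these genes, the cardiac stress list lay higher after TAC in WT hearts, with a median log2 fold change of 0.68 over 16 members (camera adjusted p = 1.56e-07, and adjusted p = 0.479 with an estimated correlation). Acta1 rose among all genes, and 9 members rose adjusted over the list alone. Nppb, which encodes B-type natriuretic peptide, stood at 223 ± 11.9 CPM in sham and 517 ± 39.6 after TAC (log2 fold change 1.21 ± 0.22, adjusted p = 0.0722), and the stretch-responsive Ankrd1 at 1.67 ± 0.34 (adjusted p = 0.0937). The extracellular matrix list lay higher too, by a median of 0.72 over 34 members (camera adjusted p = 3.75e-08, and adjusted p = 0.602 with an estimated correlation). Tnc rose among all genes and 14 members adjusted over the list alone. Values of members that missed the threshold were 4.16 ± 0.87 for the protease inhibitor Timp1 (adjusted p = 0.101) and 1.05 ± 0.19 for the collagen cross-linker Loxl2 (adjusted p = 0.0705).

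Immune lists also lay higher after TAC in WT. All 29 interferon response genes had positive fold changes, with a median of 1.05 (camera adjusted p = 3.12e-10, and adjusted p = 0.602 with an estimated correlation). Without WT TAC replicate 1 the median was 0.45 (camera adjusted p = 9.06e-06). None passed among all genes and 17 rose adjusted over the list alone, with Isg15 at 1.58 ± 0.40 and Zbp1 at 2.21 ± 0.57. With WT TAC replicate 1 left out, Isg15 stood at 0.91 and Zbp1 at 1.39. Pan-macrophage markers had a median of 0.44 over 20 members (camera adjusted p = 6.61e-05, and adjusted p = 0.479 with an estimated correlation), with 0 past the test among all genes and 7 risen adjusted over the list alone. The scavenger receptor Msr1 stood at 0.83 ± 0.17 (adjusted p = 0.0990) and the complement gene C1qa at 0.72 ± 0.16 (adjusted p = 0.123).

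Clock genes differed in opposite directions between sham and TAC in WT. The output genes Dbp and Ciart stood at 4.06 ± 0.74 and 2.29 ± 0.37, the repressor Nr1d1 at 1.55 ± 0.25, and the activator Arntl (Bmal1) at −2.16 ± 0.41, with adjusted p from 0.0548 to 0.0722. Over the list of 16, 0 passed among all genes, and 9 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0454, and adjusted p = 0.479 with an estimated correlation). The camera call ended without WT sham replicate 3 (adjusted p = 0.113), WT TAC replicate 3 (0.119), WT TAC replicate 5 (0.179) or KO TAC replicate 1 (0.0561). Atrial genes lay lower, by a median of −3.17 over 11 members (camera adjusted p = 0.000223, and adjusted p = 0.602 with an estimated correlation), with 0 past the test among all genes and 7 fallen adjusted over the list alone. The atrial myosin light chain Myl7 stood at 137 ± 206 CPM in WT sham and 1.30 ± 1.53 CPM in WT TAC hearts (log2 fold change −6.73 ± 1.67, adjusted p = 0.138). The share of atrial tissue in each sample was not measured, and Myl7 had 375 CPM in WT sham replicate 2 and at most 27.8 CPM in the other 2 WT sham libraries. With replicate 2 left out, Myl7 stood at −3.83 and the median of the list at −0.92 (camera adjusted p = 0.00239). The values were −8.36 and −4.34 without WT TAC replicate 3. Mesothelial markers (median −2.96, camera adjusted p = 0.119) and adipocyte markers (median −1.78, camera adjusted p = 0.732) also had negative medians, and neither list was called with all libraries. The mesothelial list was called without WT sham replicate 3 (camera adjusted p = 0.00307, and adjusted p = 0.762 with an estimated correlation).

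Camera called 3 further lists as higher for TAC in WT. Apoptosis genes had a median of 0.32 (camera adjusted p = 0.00852, and adjusted p = 0.479 with an estimated correlation). Nuclear respiratory chain genes had a median of 0.20 (camera adjusted p = 0.0297, and adjusted p = 0.897 with an estimated correlation). Cell cycle genes had a median of 0.85 (camera adjusted p = 0.0454, and adjusted p = 0.897 with an estimated correlation). No member of these lists passed among all genes. Adjusted over the list alone, 4 apoptosis genes rose, 0 respiratory chain genes passed, and 3 cell cycle genes rose and 1 fell. The respiratory chain call ended without WT sham replicate 2 (adjusted p = 0.134) or WT TAC replicate 3 (0.0729). The cell cycle call ended without WT sham replicate 2 (0.105) or WT TAC replicate 1 (0.346) or 5 (0.661). It also ended without KO sham replicate 1 (0.0749), 2 (0.0568) or 3 (0.0514), or KO TAC replicate 1 (0.0507) or 5 (0.0550).

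In KO hearts no gene passed for TAC against sham, in a sham group of which replicate 1 lay with the KO TAC libraries. The 4 smallest p belonged to Prrg1 at −0.92 ± 0.13, the matrix glycoprotein Myoc at 1.83 ± 0.26, the B-cell chemokine Cxcl13 at 4.65 ± 0.69 and Spaca6 at −1.07 ± 0.17, each with an adjusted p of 0.103. All 4 passed without KO sham replicate 1, Prrg1 at −0.94, Myoc at 1.84, Cxcl13 at 6.05 and Spaca6 at −1.16, with adjusted p up to 0.000514. Cxcl13 stood at 3.99 without KO sham replicate 2 (adjusted p = 0.399). Cxcl13 stood at 0.0839 ± 0.107 CPM in KO sham and 1.90 ± 0.662 CPM in KO TAC hearts, and Myoc at 3.42 ± 0.229 and 12.2 ± 2.88 CPM (SD, n = 3). The fatty acid dehydrogenase Acadvl stood at −3.05 ± 0.74 with all libraries (adjusted p = 0.103) and fell by 3.58 without KO sham replicate 1 (adjusted p = 9.4e-05).

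edgeR called 0 genes for TAC in KO and had 4878 at an unadjusted p under 0.05. DESeq2 called 1863, limma-voom 9991 and edgeR without the low-count filter 687. The count was 7708 without KO sham replicate 1, 3634 higher and 4074 lower, and 1 without WT TAC replicate 1. Camera also called 3 further lists with KO sham replicate 1 left out: nuclear respiratory chain genes (median −0.62, camera adjusted p = 0.0155, 16 fallen and 4 risen among all genes), contractile and calcium handling genes (−0.69, 0.0461, 14 fallen and 4 risen) and immediate early genes (1.25, 0.0461, 8 risen). With an estimated correlation these were lost, at an adjusted p = 0.743, 0.730 and 0.743.

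Fatty acid oxidation genes lay lower after TAC in KO, with a median of −0.88 over 30 members (camera adjusted p = 0.000258, and adjusted p = 0.907 with an estimated correlation). No member passed among all genes, and 19 fell and 1 rose adjusted over the list alone; without KO sham replicate 1, 25 fell and 1 rose among all genes. Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, stood at −2.02 ± 0.54 (adjusted p = 0.103). It fell by 2.50 without KO sham replicate 1 (adjusted p = 9.4e-05). Citric acid cycle genes were negative in 18 of 18 members, with a median of −1.29 (camera adjusted p = 0.000258, and adjusted p = 0.907 with an estimated correlation), and 0 passed among all genes against 13 fallen adjusted over the list alone. Without KO sham replicate 1, 17 of the 18 fell among all genes. The 13 genes of the mitochondrial genome went the other way, with a median of 0.53 (camera adjusted p = 0.00661, and adjusted p = 0.907 with an estimated correlation) and 0 past the test among all genes or adjusted over the list alone. Glycolysis genes had a median of −0.55 (camera adjusted p = 0.0215, and adjusted p = 0.907 with an estimated correlation). None passed among all genes and 7 fell adjusted over the list alone. The call ended without KO sham replicate 2 (adjusted p = 0.0549) or 3 (0.0593). The median was −0.88 for glycolysis genes and 0.94 for mitochondrially encoded genes without KO sham replicate 1.

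Resident macrophage markers lay higher after TAC in KO, with a median of 0.33 over 18 members (camera adjusted p = 0.0215, and adjusted p = 0.907 with an estimated correlation). No member passed among all genes and 3 rose adjusted over the list alone; without KO sham replicate 1, 12 rose and 2 fell among all genes. The complement receptor Vsig4 stood at 2.16 ± 0.52, the phosphatidylserine receptor Timd4 at 0.84 ± 0.26 and the hyaluronan receptor Lyve1 at 0.59 ± 0.19, each with an adjusted p of 0.103. These 3 passed without KO sham replicate 1, at 3.17, 0.90 and 0.69, with adjusted p of 0.000164 for Vsig4, 0.0205 for Timd4 and 0.0121 for Lyve1. Inflammatory cytokines and chemokines had a median of 0.70 (camera adjusted p = 0.0315, and adjusted p = 0.907 with an estimated correlation), with 1 risen and 1 fallen adjusted over the list alone and 0 among all genes. This call ended without KO sham replicate 2 (adjusted p = 0.0599) or KO TAC replicate 5 (0.118). The 5 tested neutrophil markers had a median of 1.13 (camera adjusted p = 0.0315, and adjusted p = 0.907 with an estimated correlation). None passed among all genes or adjusted over the list alone, and the call ended without KO sham replicate 2 (0.0549) or KO TAC replicate 3 (0.0531). Medians without KO sham replicate 1 were 0.66 for resident macrophage markers, 1.23 for cytokines and chemokines and 1.71 for neutrophil markers.

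The clock genes stood in the same directions in KO as in WT: Arntl at −2.20 ± 0.42, its partner Npas2 at −1.57 ± 0.32, Tef at 1.56 ± 0.35 and Ciart at 1.60 ± 0.36, each with an adjusted p of 0.103. They passed without KO sham replicate 1, Arntl at −2.47, Npas2 at −1.63, Tef at 2.21 and Ciart at 2.18, with adjusted p up to 0.00188. Over the 16, 0 passed among all genes, 7 rose and 5 fell adjusted over the list alone, and camera did not call the list (adjusted p = 0.118). The cardiac stress list was not called in KO (median −0.23, camera adjusted p = 0.718), with 1 risen and 1 fallen adjusted over the list alone and 0 among all genes. Its members with the smallest p were Nmrk2 at −0.76 ± 0.21 and the slow myosin Myh7 at 0.78 ± 0.23, each with an adjusted p of 0.103. Both passed without KO sham replicate 1, Nmrk2 at −0.82 (adjusted p = 0.00959) and Myh7 at 0.94 (adjusted p = 0.00414).

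Between the genotypes after sham, Cnmd (ENSMUSG00000022025), the matrix-bound angiogenesis inhibitor chondromodulin, fell 7.72-fold in KO, from 1.44 ± 0.345 to 0.176 ± 0.0358 CPM (SD, n = 3; log2 fold change −2.95 ± 0.36, adjusted p = 0.0479). All 34 extracellular matrix genes had positive fold changes in KO sham hearts, with a median of 1.12 (camera adjusted p = 2.34e-17, and adjusted p = 0.584 with an estimated correlation). No member passed among all genes and 30 rose adjusted over the list alone. The collagen-binding Sparc stood at 273 ± 30.8 CPM in WT and 701 ± 124 CPM in KO (log2 fold change 1.36 ± 0.25, adjusted p = 0.101), and thrombospondin 1, Thbs1, at 1.91 ± 0.37 (adjusted p = 0.118).

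Cnmd was the only gene edgeR called, with 2138 at an unadjusted p under 0.05. DESeq2 called 207, limma-voom 2351 and edgeR without the low-count filter 80, while edgeR with library totals, with a minimum of 1 CPM or on the 6 sham libraries alone called 0. Cnmd passed without KO sham replicate 1, when 39 genes were called, and without WT TAC replicate 3, when 4 were. Without KO sham replicate 2 a different gene was the only call, and no gene passed without KO sham replicate 3, WT TAC replicate 1 or 5, or any WT sham or KO TAC library. The adjusted p of Cnmd was at most 0.316, without KO sham replicate 3.

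Immediate early genes lay higher in KO sham hearts, with a median of 0.90 over 17 members (camera adjusted p = 0.000105, and adjusted p = 0.584 with an estimated correlation). The median was 0.22 without KO sham replicate 1 (camera adjusted p = 0.00998). None passed among all genes and 6 rose adjusted over the list alone. The nuclear receptor Nr4a3 stood at 3.61 ± 0.64 (adjusted p = 0.101) and the flow-responsive Klf2 at 1.27 ± 0.32 (adjusted p = 0.241). Cell cycle genes had a median of 1.22 (camera adjusted p = 3.52e-07, and adjusted p = 0.584 with an estimated correlation), with 6 risen and 1 fallen adjusted over the list alone and 0 among all genes. The kinesin Kif11 stood at 1.57 ± 0.35 and the kinetochore gene Cenpf at −2.11 ± 0.32 (adjusted p = 0.0757). Pan-macrophage markers were positive in 20 of 20 members, with a median of 0.38 (camera adjusted p = 6.86e-05, and adjusted p = 0.584 with an estimated correlation), and 4 rose adjusted over the list alone against 0 among all genes. Contractile and calcium handling genes lay lower, with a median of −0.42 over 24 members (camera adjusted p = 3.52e-07, and adjusted p = 0.584 with an estimated correlation) and 0 past the test among all genes or adjusted over the list alone. The potassium channel gene Kcnj2 stood at −1.18 ± 0.35 and troponin T, Tnnt2, at −0.61 ± 0.19.

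Another 7 lists were called after sham, each with an adjusted p = 0.584 with an estimated correlation. Interferon response genes (median 0.88, camera adjusted p = 2.37e-08) and TGF-beta signalling genes (median 0.39, camera adjusted p = 0.00132) lay higher in KO, with 4 and 2 members risen adjusted over the list alone. Endothelial markers (median 0.40, camera adjusted p = 0.00225) and apoptosis genes (median 0.41, camera adjusted p = 0.00537) lay higher as well, with 0 and 1 risen adjusted over the list alone. Fatty acid oxidation genes lay lower, with a median of −0.49 and a camera adjusted p of 1.19e-05. Citric acid cycle genes had a median of −0.45 (camera adjusted p = 0.000111) and nuclear respiratory chain genes −0.30 (camera adjusted p = 0.00190). In these 3 lists 0 passed adjusted over the list alone. No member of these lists passed among all genes. Without KO sham replicate 1 the calls ended for fatty acid oxidation (camera adjusted p = 0.147), the citric acid cycle (0.604), the respiratory chain (0.402), apoptosis (0.0903) and endothelial markers (0.0681). Their medians were then −0.14, −0.04, −0.04, 0.22 and 0.18. The TGF-beta call stayed (0.00497), with a median of 0.17. The respiratory chain call also ended without WT sham replicate 3 (0.102). Other lists were called only with a library left out. Mitochondrially encoded genes (median −0.50, camera adjusted p = 4.61e-06) and neutrophil markers (−1.90, 0.00495) lay lower without KO sham replicate 1, each with an adjusted p = 0.517 with an estimated correlation. Atrial genes (3.05, 0.000135) and adipocyte markers (1.67, 0.00133) lay higher without WT sham replicate 2, each with an adjusted p = 0.537 with an estimated correlation.

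After TAC, the genes called between the genotypes included genes of mitochondrial metabolism, contraction and the atrium. Each of the 17 list calls was lost with an estimated correlation (camera adjusted p = 0.486 to 0.610). In KO TAC hearts the fatty acid dehydrogenase Acadvl (ENSMUSG00000018574) fell 8.06-fold, from 233 ± 129 to 28.9 ± 2.97 CPM, and Bckdha (ENSMUSG00000060376), which breaks down branched-chain amino acids, fell 7.91-fold, from 40.3 ± 24.4 to 5.07 ± 1.01 CPM. Cardiac alpha-actin, Actc1 (ENSMUSG00000068614), fell 3.58-fold, from 7671 ± 1753 to 2144 ± 119 CPM, and the fatty acid carrier Fabp3 3.27-fold, from 2911 ± 218 to 889 ± 33.5 CPM. The atrial growth factor Bmp10 (ENSMUSG00000030046) rose from 2 to 1101 counts over 3 libraries, a ratio of 742 (95% counting interval 205 to 6132), and Myl7 304-fold, from 1.30 ± 1.53 to 394 ± 255 CPM (SD, n = 3). The share of atrial tissue in each sample was not measured.

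Mitochondrially encoded transcripts made up 44.0 to 51.3% of the counts in KO TAC and 24.8 to 32.5% in WT TAC libraries. Of the 15804 genes tested, edgeR called 3219 for genotype after TAC, 1364 higher and 1855 lower in KO, and 6444 at an unadjusted p under 0.05. Scaled by library totals, 3525 were called, 515 higher and 3010 lower. limma-voom called 7648, and 1538 of the edgeR calls changed over 2-fold. Leaving out 1 library gave 85 calls without WT TAC replicate 3, 166 without WT TAC replicate 5, and 58, 43 and 437 without KO TAC replicate 1, 3 and 5. It gave 1716, 1903 and 2076 without WT sham replicate 1, 2 and 3, 5425 without WT TAC replicate 1 and 6585 without KO sham replicate 1. Of the 73 called genes that the naming rule takes here, 5, 6 and 21 passed without KO TAC replicate 1, 3 and 5, and 7 and 11 without WT TAC replicate 3 and 5. There were 60, 62 and 64 without WT sham replicate 1, 2 and 3, 69 without WT TAC replicate 1 and 70 without KO sham replicate 3. Cd163, Nmrk2 and Tnfaip3 passed with each of the 12 libraries left out, and the highest adjusted p of any of the 73 was 0.153, for Cd68 without KO TAC replicate 1. Without the low-count filter 56 of the 73 passed and 17 did not. Among the 17 were Sln, Myl4, Nkain1, Acadvl, Bckdha, Schip1, Thtpa, Sdr39u1, Fmod, Thbs1, Uqcrc2, mt-Co1, Aldoa, Laptm5, Cd68 and Atf3. With a fit that was not robust, mt-Co1 did not pass.

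Among the genes with the largest falls, Nkain1 stood at −3.07 ± 0.75, Acadvl at −3.01 ± 0.73, Bckdha at −2.98 ± 0.76, and Schip1 at −2.84 ± 0.86. The thiamine triphosphatase Thtpa stood at −2.83 ± 0.88, Cpn2 at −2.74 ± 0.73 and Sdr39u1 at −2.73 ± 0.64. Their adjusted p ran from 0.0233 to 0.0432. The pseudogene Gapdh-ps15, at −2.78 ± 0.78, shares sequence with Gapdh and is uncertain. These did not pass when a library was left out: Thtpa at −3.79 without KO TAC replicate 1, Cpn2 at −3.46 without KO TAC replicate 5, and Gapdh-ps15 at −2.08 without WT TAC replicate 1. Among those with the largest rises, Alox8, Chodl and Plppr5 had 0 counts over the WT TAC libraries and were at least 35.0-fold, 26.5-fold and 24.7-fold higher in KO TAC. Alox8 did not pass without KO TAC replicate 1 (edgeR adjusted p = 0.0608), which held 46 of its 78 KO TAC counts. Hamp, which encodes the iron hormone hepcidin, rose from 2 counts, under the floor, to 325 counts, a ratio of 219 (95% counting interval 60.1 to 1815, edgeR adjusted p = 0.0116). Within the WT sham, the KO sham and the KO TAC group, the library with the most Hamp also had the most Myl7.

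Fatty acid oxidation genes lay lower in KO TAC, by a median of −1.28 over 30 members (camera adjusted p = 5.4e-07, and adjusted p = 0.486 with an estimated correlation). Among all genes 20 fell, and 24 adjusted over the list alone. The log2 fold changes were −1.71 ± 0.32 for Fabp3 (adjusted p = 0.0165), −1.28 ± 0.26 for the fatty acid transporter Cd36, −1.22 ± 0.26 for the uncoupling protein gene Ucp3 and −1.44 ± 0.32 for Acot2. Citric acid cycle genes lay lower in 18 of 18 members, by a median of −1.48 (camera adjusted p = 3.47e-06, and adjusted p = 0.486 with an estimated correlation). Among all genes 12 fell, and 18 adjusted over the list alone, among them Idh3b (−1.88 ± 0.44), fumarate hydratase Fh1 (−1.45 ± 0.33) and the succinate dehydrogenase subunit Sdhc (−1.43 ± 0.37). Nuclear respiratory chain genes had a median of −0.64 over 25 members (camera adjusted p = 0.000123, and adjusted p = 0.486 with an estimated correlation). Among all genes 11 fell, and 14 adjusted over the list alone. The complex III subunit Uqcrc2 fell 5.37-fold (adjusted p = 0.0244), with Cox5a at −1.39 ± 0.32, Ndufs3 at −1.03 ± 0.23 and Ndufv2 at −0.99 ± 0.23. The 13 mitochondrially encoded genes went the other way, by a median of 0.85 (camera adjusted p = 0.000539, and adjusted p = 0.531 with an estimated correlation). The NADH dehydrogenase subunit mt-Nd5 (1.54 ± 0.34) and the cytochrome oxidase subunit mt-Co1 (1.05 ± 0.34) rose among all genes, and 1 gene rose adjusted over the list alone. Glycolysis genes lay lower, by a median of −0.72 over 19 members (camera adjusted p = 0.000131, and adjusted p = 0.486 with an estimated correlation). Among all genes 10 fell, and 14 fell and 1 rose adjusted over the list alone. The log2 fold changes were −1.34 ± 0.31 for the hexokinase Hk1, −1.41 ± 0.37 for the lactate dehydrogenase Ldhb, −1.21 ± 0.32 for Tpi1 and −0.72 ± 0.19 for the aldolase Aldoa.

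**Figure D3:**
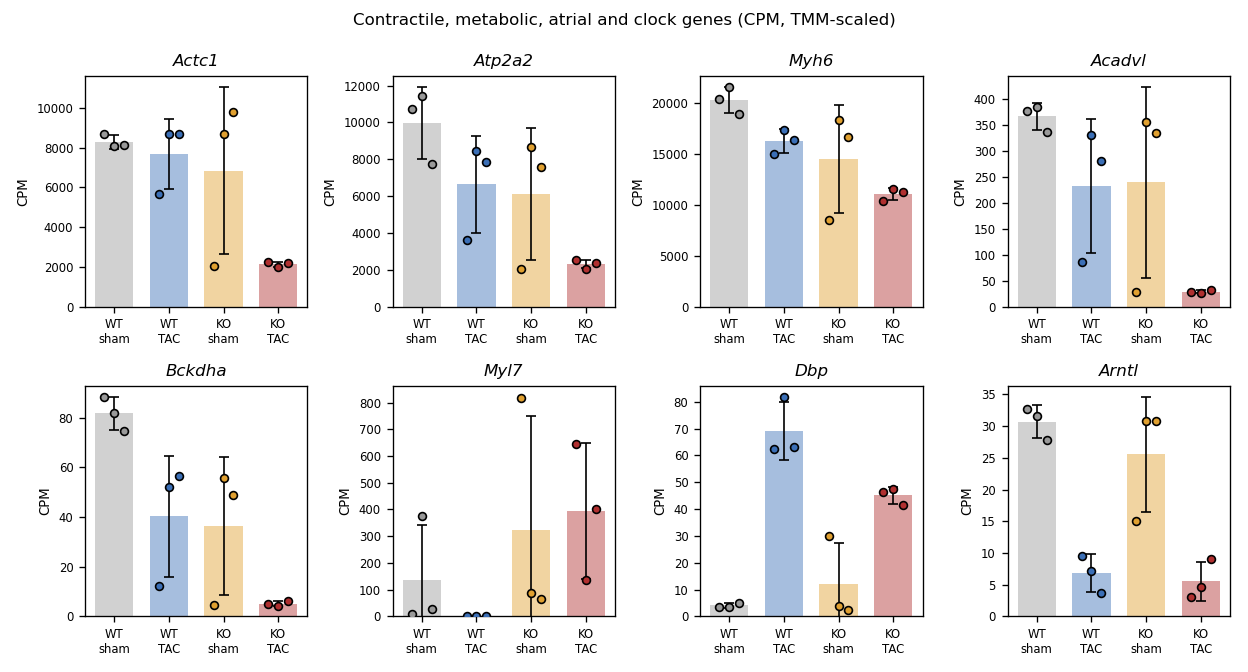
CPM of contractile (Actc1, Atp2a2, Myh6), metabolic (Acadvl, Bckdha), atrial (Myl7) and clock (Dbp, Arntl) genes in the 4 groups, chosen for display after their values were seen; bars are means, whiskers SD and points the 3 libraries of a group. For Actc1, Atp2a2, Acadvl and Bckdha, KO sham replicate 1 lies near the 3 KO TAC libraries and apart from the other KO sham libraries.

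Heart muscle genes lay lower in KO TAC. Contractile and calcium handling genes had a median of −0.67 over 24 members (camera adjusted p = 0.00252, and adjusted p = 0.486 with an estimated correlation). Among all genes 8 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone. Actc1 stood at −1.84 ± 0.45, the inward rectifier channel gene Kcnj2 at −1.90 ± 0.37 and the calcium-binding calsequestrin gene Casq2 at −1.44 ± 0.35, while the channel gene Kcnd3 rose by 1.24. Cardiac stress genes lay lower in KO TAC than in WT TAC, by a median of −0.85 over 16 members (camera adjusted p = 0.00109, and adjusted p = 0.486 with an estimated correlation). Among all genes 8 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone. Nmrk2, a nicotinamide riboside kinase induced in stressed muscle, fell 2.89-fold (adjusted p = 0.0102), the small heat shock protein gene Hspb7 3.63-fold (adjusted p = 0.0116), and the desmin gene Des stood at −1.21 ± 0.22 and Fhl1 at −1.59 ± 0.32. Antioxidant genes lay lower, by a median of −0.52 over 24 members (camera adjusted p = 0.0163, and adjusted p = 0.486 with an estimated correlation). Among all genes 12 fell and 2 rose, and 13 fell and 2 rose adjusted over the list alone. The glutathione transferase Gsta4 fell by 1.38 (adjusted p = 0.0116), and catalase, Cat, stood at −1.58 ± 0.37 and Nqo1 at −1.11 ± 0.25.

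Atrial genes lay higher in KO TAC in 11 of 11 members, by a median of 5.52 (camera adjusted p = 0.000110, and adjusted p = 0.486 with an estimated correlation), and 8 rose both among all genes and adjusted over the list alone. Besides Bmp10 and Myl7, Myl4 rose by 6.90 and sarcolipin, Sln, by 7.76. Bmp10, Myl7 and Sln were not called by limma-voom. Without WT TAC replicate 3 they did not pass, with Myl7 at 9.87, Sln at 8.77 and no count of Bmp10 left in WT TAC. The median of the list was 4.70 without KO TAC replicate 1. Among adipocyte markers, 6 rose and 1 fell among all genes, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0321, and adjusted p = 0.486 with an estimated correlation). The adipokine complement factor D, Cfd, rose from 0.266 ± 0.237 to 13.1 ± 2.07 CPM, Cidec by 4.59 and Plin1 by 4.39, while Cidea fell by 1.02. Cfd, at 6.58, and Plin1, at 5.62, did not pass without WT TAC replicate 3, nor did Cidec, at 5.53, without WT TAC replicate 5. The adipocyte call ended without KO sham replicate 1 (camera adjusted p = 0.0689) or WT TAC replicate 1 (0.0921). Immediate early genes lay higher, by a median of 1.97 over 17 members (camera adjusted p = 0.000123, and adjusted p = 0.486 with an estimated correlation). The median was 1.22 without KO TAC replicate 5. Of these, 8 rose among all genes and 15 adjusted over the list alone, among them Klf4 (1.35 ± 0.24), Klf2 (1.52 ± 0.32), Atf3 (1.97 ± 0.47) and Dusp1 (1.45 ± 0.39).

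Resident macrophage markers lay higher in KO TAC, by a median of 0.58 over 18 members (camera adjusted p = 0.00125, and adjusted p = 0.486 with an estimated correlation). Of these, 4 rose among all genes and 6 adjusted over the list alone. Timd4 rose 2.54-fold, from 1.25 ± 0.425 to 3.20 ± 0.333 CPM (adjusted p = 0.0176), the scavenger receptor Stab1 by 1.08, the transcription factor Maf by 1.05 and Lyve1 by 0.64. Pan-macrophage markers were not called (median −0.15, camera adjusted p = 0.622), with Laptm5 risen by 0.60, Cd68 fallen (−0.52 ± 0.17) and 0 past the test adjusted over the list alone. With library totals in place of TMM, Stab1, Lyve1, Maf and Laptm5 were not called. Among cytokines and chemokines, 2 rose and 1 fell both among all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.138). It was called without KO TAC replicate 1 (0.0467) or WT TAC replicate 3 (0.0235), with adjusted p = 0.553 and 0.512 with an estimated correlation. Cxcl13 rose 14.8-fold (adjusted p = 0.0116) and Ccl24, a chemokine for eosinophils, by 1.32, while Cxcl14 fell by 0.82.

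Of 16 tested interleukin-10 axis genes, Tnfaip3, a brake on NF-kappaB signalling, rose 2.72-fold in KO TAC, from 2.54 ± 0.273 to 6.92 ± 1.61 CPM (adjusted p = 0.0108). The interleukin-4 receptor gene Il4ra rose by 0.77 (adjusted p = 0.0363) but was not called with library totals. These 2 also rose adjusted over the list alone, and the list was not called (camera adjusted p = 0.256). The haem oxygenase gene Hmox1, which acts downstream of haemoglobin uptake, stood at −0.86 ± 0.30 (adjusted p = 0.0574). Haemoglobin, haem and iron handling genes were not called (camera adjusted p = 0.969; median −0.29 and mean 0.40, of opposite sign), with 5 risen and 3 fallen among all genes and 5 risen and 5 fallen adjusted over the list alone. Besides Hamp, transferrin, Trf, rose by 0.83, while ceruloplasmin, Cp, fell by 0.79 and the haem transporter Slc48a1 stood at −0.72 ± 0.20. Extracellular matrix genes were not called (median 0.14, camera adjusted p = 0.178), with 3 risen and 2 fallen both among all genes and adjusted over the list alone. The list was called without WT TAC replicate 5 (median 0.49, camera adjusted p = 0.000326, and adjusted p = 0.581 with an estimated correlation). Tnc fell by 1.95, fibromodulin, Fmod, rose by 3.12, the ion channel gene Piezo2 by 2.03 and Thbs1 by 1.20, which was not called with library totals. Fmod rose by 5.11 without WT TAC replicate 5 and Piezo2 by 2.75 without WT TAC replicate 1.

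Camera called 5 further lists as higher in KO after TAC. B cell markers had a median of 0.78 (camera adjusted p = 0.00583, and adjusted p = 0.486 with an estimated correlation). Endothelial markers had a median of 0.50 (camera adjusted p = 0.00767, and adjusted p = 0.535 with an estimated correlation) and mesothelial markers of 3.26 (camera adjusted p = 0.0163, and adjusted p = 0.610 with an estimated correlation). In these lists 2, 1 and 1 members rose both among all genes and adjusted over the list alone. TGF-beta signalling genes had a median of 0.40 (camera adjusted p = 0.0163, and adjusted p = 0.486 with an estimated correlation), with 4 risen among all genes and 5 adjusted over the list alone. Fibroblast markers had a median of 0.23 (camera adjusted p = 0.0350, and adjusted p = 0.540 with an estimated correlation), with 4 risen in both counts. Without WT TAC replicate 1 the calls ended for TGF-beta signalling (camera adjusted p = 0.169), mesothelial (0.169) and fibroblast markers (0.102). The fibroblast call also ended without WT TAC replicate 3 (0.134), KO sham replicate 1 (0.0689) or KO sham replicate 3 (0.0507). The mesothelial median was 2.67 without WT TAC replicate 1. Interferon response genes were not called (median 0.06, camera adjusted p = 0.256) but were called without WT TAC replicate 1 (median 0.75, camera adjusted p = 0.000349, and adjusted p = 0.673 with an estimated correlation).

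Whether the genotype changed the response to TAC was tested as an interaction, and no gene passed. Among the 4 genes with the smallest p were Enpp2, at 1.97 ± 0.25 with an adjusted p of 0.0545, and the macrophage product Retnla at 3.05 ± 0.40. The others were the opioid precursor gene Penk at 2.49 ± 0.36 and the predicted gene Gm12183 at 1.32 ± 0.19, with adjusted p up to 0.0633. Enpp2 stood at 12.5 ± 2.15 CPM in sham and 4.61 ± 0.207 after TAC in WT, and at 8.60 ± 0.608 and 12.5 ± 2.41 CPM in KO. Retnla stood at 4.15 ± 0.442 and 1.26 ± 0.379 CPM in WT, and at 2.47 ± 0.897 and 6.17 ± 0.746 CPM in KO (SD, n = 3).

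For the interaction, edgeR called 0 genes and had 1452 at an unadjusted p under 0.05. DESeq2 called 94, limma-voom 5056, edgeR without the low-count filter 43 and with library totals 7. The count was 1961 without KO sham replicate 1, 754 more positive in KO and 1207 more negative, and 4 without WT TAC replicate 1. Cd163 had an interaction of −0.80 ± 0.38 (adjusted p = 0.553). No gene was called for TAC in both genotypes, and 704 were called in the same direction without KO sham replicate 1, with 371 higher in both against 123 for independent lists and 333 lower in both against 128. Another 50 were called in opposite directions. Both contrasts share each gene's spread in the fit, so the counts for independent lists are no measure of a common response. Without both KO sham replicate 1 and WT TAC replicate 1, 524 were called in the same and 163 in opposite directions. The Pearson r of the TAC fold changes between the genotypes was 0.441 with all libraries, 0.461 without KO sham replicate 1 and 0.222 without both.

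Camera called 16 lists for the interaction, and each call was lost with an estimated correlation and with fry for direction. The cardiac stress list had a median interaction of −0.91 (camera adjusted p = 5.34e-07, and adjusted p = 0.652 with an estimated correlation). None of its genes passed among all genes, and 8 were negative and 1 positive adjusted over the list alone, with Acta1 at −2.91 ± 0.55 (adjusted p = 0.162) and Nppb at −1.48 ± 0.31. Extracellular matrix genes had a median of −1.07 (camera adjusted p = 5.34e-07, and adjusted p = 0.766 with an estimated correlation). No member passed among all genes and 12 were negative adjusted over the list alone, with Tnc at −3.92 ± 0.71 and Loxl2 at −1.58 ± 0.27 (adjusted p = 0.125). The mitochondrially encoded genes were positive in 13 of 13 members, with a median of 0.90 (camera adjusted p = 7.26e-07, and adjusted p = 0.675 with an estimated correlation). The gene mt-Nd5 stood at 1.59 ± 0.48 (adjusted p = 0.428), with 0 past the test among all genes or adjusted over the list alone. Extracellular matrix genes already lay higher in KO after sham (median 1.12), and after TAC the genotypes differed by a median of 0.14. The extracellular matrix call ended without both KO sham replicate 1 and WT TAC replicate 1 (camera adjusted p = 0.136). With only KO sham replicate 1 left out, the median was −0.71 for extracellular matrix genes (camera adjusted p = 0.0424) and 1.47 for mitochondrially encoded genes. The other 13 calls had camera adjusted p from 2.01e-06 to 0.0297.

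Several lists were called in none of the 5 comparisons with all libraries. Their lowest camera adjusted p were 0.0599 for angiogenesis genes after TAC in WT. For genotype after sham they were 0.0854 for T cell markers, 0.192 for skeletal muscle genes, 0.245 for interleukin-10 axis genes, 0.271 for erythroid genes, 0.285 for smooth muscle and pericyte markers and 0.387 for haemoglobin, haem and iron handling genes. For TAC in KO they were 0.294 for endoplasmic reticulum stress genes and 0.416 for monocyte-derived and antigen-presenting macrophage markers. Of these lists, members passed among all genes after TAC between the genotypes only, with 4 angiogenesis genes risen and 1 fallen, besides interleukin-10 axis and haem genes. There, 2 endoplasmic reticulum stress genes and 1 skeletal muscle gene rose, and 1 erythroid, 1 smooth muscle and 1 monocyte-derived macrophage marker fell. Adjusted over the list alone in that comparison, 5 angiogenesis genes rose and 2 fell, 2 stress genes and 1 skeletal muscle gene rose, 2 erythroid genes fell and 0 of the smooth muscle and monocyte-derived markers passed. Of lung epithelial and liver genes, 1 and 2 were tested, too few for a list test, and 1 liver gene rose in KO after TAC. With a library left out, some of the lists named first in this paragraph were called. Angiogenesis genes for TAC in WT were called without WT sham replicate 2 (camera adjusted p = 0.0209), WT TAC replicate 1 (0.0208) or KO TAC replicate 3 (0.0495), and erythroid genes without WT sham replicate 2 (0.0463). For genotype after sham, T cell markers were called without WT sham replicate 1 (0.0266) or KO sham replicate 3 (0.0320), and skeletal muscle (0.0228) and erythroid genes (0.0492) without WT sham replicate 2. After TAC, T cell markers were called without KO TAC replicate 1 (0.0467). These calls were lost too, at an adjusted p = 0.288 or more with an estimated correlation. The median, the mean or the test of a list differed in sign only in uncalled tests: for monocyte-derived and skeletal muscle lists in 3 comparisons each, neutrophil and haem lists in 2 each. It did so in 1 comparison each for pan-macrophage, mesothelial, fibroblast, smooth muscle, erythroid, cell cycle, interleukin-10, T cell, angiogenesis, contractile, TGF-beta, immediate early and mitochondrially encoded lists.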

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

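All tests of explanations in this part were chosen after the values had been seen, except the counts over other splits of the samples.

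The response to TAC differed between the genotypes in 16 gene lists by camera on the interaction, 6 more positive in KO and 10 more negative, and each call was lost with an estimated correlation, where the lowest adjusted p was 0.652. Fry for direction also lost all 16. The lower responses were those of cardiac stress genes (median −0.91, camera adjusted p = 5.34e-07), extracellular matrix genes (−1.07, 5.34e-07), pan-macrophage markers (−0.57, 0.000218), glycolysis genes (−0.53, 0.000937), interferon response genes (−0.66, 0.00128), fatty acid oxidation genes (−0.90, 0.00152), citric acid cycle genes (−0.99, 0.00158), cell cycle genes (−1.17, 0.00158), nuclear respiratory chain genes (−0.41, 0.00960) and antioxidant genes (−0.40, 0.0265). The higher responses were those of mitochondrially encoded genes (0.90, 7.26e-07), atrial genes (5.11, 2.01e-06), resident macrophage markers (0.17, 0.0289), adipocyte markers (2.98, 0.0289), Schwann cell and neuronal markers (0.71, 0.0295) and mesothelial markers (2.57, 0.0297). No member passed among all genes. Adjusted over the list alone, 2 fatty acid oxidation genes, 1 glycolysis gene and 1 pan-macrophage marker were negative, 6 atrial genes, 2 resident macrophage and 1 Schwann cell marker were positive, and adipocyte markers had 3 positive and 1 negative. Extracellular matrix, interferon, cell cycle and pan-macrophage lists already lay higher in KO after sham, with medians of 1.12, 0.88, 1.22 and 0.38. Between the genotypes after TAC they were not called, with medians of 0.14, 0.06, 0.05 and −0.15. Their lower response thus went with a higher level in KO sham hearts, KO sham replicate 1 included, and not with a called fall in KO TAC. The higher response of atrial genes went with a lower level after TAC in WT (median −3.17). For TAC in KO the atrial list was not called (median 0.29, camera adjusted p = 0.318).

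Single libraries ended some of these calls. Without KO sham replicate 1 the camera adjusted p was 0.216 for interferon, 0.0579 for antioxidant, 0.143 for cell cycle, 0.0917 for adipocyte and 0.109 for Schwann cell lists. Without KO sham replicate 2 it was 0.0868 for fatty acid oxidation, 0.0949 for the citric acid cycle, 0.0868 for the respiratory chain, 0.102 for resident macrophage, 0.0552 for adipocyte and 0.407 for mesothelial lists. Without KO sham replicate 3 it was 0.0568 for fatty acid oxidation, the citric acid cycle and mesothelial markers, 0.0629 for the respiratory chain and 0.0662 for resident macrophages. Without WT TAC replicate 1 it was 0.114 for the respiratory chain, 0.0838 for resident macrophages, 0.632 for interferon, 0.111 for cell cycle, 0.117 for adipocyte and 0.363 for mesothelial lists. Without WT TAC replicate 3 it was 0.112 for resident macrophages and 0.0674 for Schwann cells, and without WT TAC replicate 5 0.158 for antioxidant and 0.0572 for cell cycle and Schwann cell lists. Mesothelial calls also ended without WT sham replicate 1 (0.104) or 2 (0.156) and KO TAC replicate 5 (0.110), and the Schwann cell call without KO TAC replicate 5 (0.104). The respiratory chain call ended without WT sham replicate 2 (0.0928), the adipocyte call without KO TAC replicate 3 (0.0554) and the resident macrophage call without WT sham replicate 3 (0.0598) or KO TAC replicate 1 (0.0881). Without both KO sham replicate 1 and WT TAC replicate 1 it was 0.136 for extracellular matrix and Schwann cell, 0.149 for pan-macrophage, 0.544 for interferon, 0.701 for cell cycle, 0.219 for adipocyte and 0.0830 for mesothelial lists. Medians moved too, to −0.01 for interferon without WT TAC replicate 1 and to 2.46 for atrial genes without WT sham replicate 2 or 4.29 without KO TAC replicate 1. The adipocyte median was 1.09 and the mesothelial median 1.85 without WT sham replicate 2, and 3.61 and 5.56 without KO sham replicate 1. The resident macrophage median was then 0.47.

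KO sham replicate 1 lay with the 3 KO TAC libraries, apart from the other KO sham libraries. A loss of RNA by transcript length was tested at a size of 1 log2 unit or more, which was not seen. The median absolute shift of all genes was 0.468 in KO TAC against WT TAC. It was 0.584 in KO sham replicate 1 against the other KO sham libraries. The size set was thus hard to reach, and the test cannot decide on a smaller loss. In KO TAC against WT TAC, the longest of 5 equal classes of transcript length lay 0.278 above the shortest (bootstrap interval 0.237 to 0.317), opposite to such a loss. In KO sham replicate 1 against the other KO sham libraries the value was −0.127 (−0.189 to −0.0696), a small shift towards such a loss. These intervals were drawn over genes, not libraries. RNA quality was not tested otherwise. Under a lower share of cardiomyocytes alone, markers of other cell types would rise alike. Medians for genotype after TAC were 0.50 for endothelial, 0.23 for fibroblast, −0.05 for smooth muscle and −0.15 for pan-macrophage markers. The highest and lowest differed by 0.655 (permutation p = 0.00071 over genes, which are not independent replicates). This cannot decide, since the other cell types may differ in share as well. A larger share of nuclear RNA cannot be told apart from the explanations below, since 8 RNAs kept in the nucleus went both ways for genotype after TAC, with a median of 0.84 (bootstrap interval −0.28 to 1.25), Malat1 at −0.74, and Neat1 at 3688 to 5038 CPM in KO TAC, 3106 in KO sham replicate 1, 2731 in WT TAC replicate 1 and 556 to 1855 in the other libraries. A wrong label on KO sham replicate 1 stays open and may account for its place: with the spread taken from the other libraries within their groups, which a lone library is assumed to share, edgeR called 0 genes for it against the 3 KO TAC libraries, as for each KO TAC library set apart in turn, and 4728 against the other 2 KO sham libraries. A difference of this heart itself is open as well and was not tested, and its clock genes lay on both sides: Dbp (29.9 CPM, against 2.53 and 3.74 in the other KO sham and 41.6 to 47.5 in KO TAC libraries), Per2, Per3 and Ciart lay towards KO TAC, Arntl (15.1, against 30.8 and 30.9, and 3.03 to 8.98) lay between, and Npas2 (8.12, against 8.81 and 9.57, and 1.79 to 3.93) lay with the sham libraries, as did Ptgds (96.8) and the 4 genes with the smallest p for TAC in KO, which were picked with this library counted as sham: Myoc (3.48, against 3.16 and 3.61, and 10.5 to 15.5), Prrg1 (14.1), Spaca6 (12.8) and Cxcl13 (0.205).

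For the 4 comparisons of 2 groups, the 10 splits of 6 libraries are too few for a share under 0.05. TAC in WT gave 5 genes and the other splits at most 0, with 1 split as large. TAC in KO gave 0 and the others at most 0, with 10 as large. Genotype gave 1 after sham and 3219 after TAC, and the others at most 0, with 1 split as large for each. For the interaction the real count was 0, so each of the 60 drawn regroupings of the genotype labels within surgery arms, the real one included, is as large by construction (60 of 60), and this decides nothing about chance. Of the 59 others, 2 called any gene, 3 and 243, and the highest, 243, points to a structure of the samples whose cause was not tested.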

How the results depend on the processing

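The setting without both KO sham replicate 1 and WT TAC replicate 1 was chosen after the data were seen; all others were planned. With DESeq2 size factors in edgeR and with a fit that was not robust, the gene counts stayed within 1.5 times. Cd163 kept its sign in the 5 comparisons under each alternative run. For TAC in WT, where 5 genes passed, the count was 44 with library totals, 515 with DESeq2, 1030 with limma-voom, 137 without the low-count filter, 89 on the 2 groups alone, 0 with a replicate block and 989 without both libraries, and 1 to 1058 with 1 library left out. For TAC in KO, with 0, it was 1863 with DESeq2, 9991 with limma-voom, 687 without the filter, 8879 without both, and 0 to 7708 with 1 left out. For genotype after sham, with 1, it was 207 with DESeq2, 2351 with limma-voom, 80 without the filter, 295 without both, 0 with library totals, a mean CPM of at least 1, the 2 groups alone or a replicate block within the surgery arm, and 0 to 39 with 1 left out. For genotype after TAC, with 3219, it was 7648 with limma-voom, 1538 over 2-fold, which is fewer by construction, 0 with the block within the arm, 8614 without both, and 43 to 6585 with 1 left out. For the interaction, with 0, it was 7 with library totals, 94 with DESeq2, 5056 with limma-voom, 43 without the filter, 5774 without both, and 0 to 1961 with 1 left out. Genes called for TAC in both genotypes went from 0 to 524 without both and 0 to 704 with 1 left out. Cd163 in sham passed with DESeq2 (−1.90), limma-voom (−1.79), no filter (−1.87) and without both (−1.73), with −1.99 to −1.74 over single libraries left out. In TAC it did not pass with the block within the arm (−2.62, adjusted p = 0.0652), and ran from −2.97 to −2.52 over single libraries left out. Camera made 61 list calls. An estimated correlation gave 0 in total, fry for direction 18, and camera with 1 library left out 53 to 67, in part of other lists. Fry for direction lost 3 of the 17 calls for genotype after TAC and 7 of the 9 for TAC in WT. It lost all 16 for the interaction, all 12 for genotype after sham and all 7 for TAC in KO. The interaction of interferon response genes turned its direction without both libraries (adjusted p = 0.544). For TAC in WT, KO sham replicate 1 is in neither group compared. Cardiac stress genes had a median of 0.683 with it and 0.681 without it, and extracellular matrix genes 0.717 and 0.714. The change from 5 to 1058 calls thus lay in the shared spread and the genes tested, not in these fold changes. Apart from this and the 2-fold minimum, the cause was not tested. No pairing by replicate number was seen: not every sample correlates best with its own number (sham −0.19, 0.06 and −0.16, TAC −0.13, −0.05 and −0.14). With 3 libraries per group this cannot exclude a batch shared by number. The blocked counts, 2411 for genotype after TAC with a block over all 12, stand here only. Depth limits Il10, at 1 to 3 counts per group.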

Other observations

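All tests in this part were chosen after the values had been seen, and so were the genes named in its first paragraph.

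Over both surgeries together, KO hearts differed from WT hearts in Cd163 and in genes of other functions. Pdcd5 (ENSMUSG00000030417), a gene linked to programmed cell death, fell 2.23-fold and the homeobox gene Irx3 (ENSMUSG00000031734), which acts in the cardiac conduction system, fell 2.42-fold. The cold-inducible RNA-binding gene Cirbp (ENSMUSG00000045193) fell 1.73-fold. The kinase gene Stk17b (ENSMUSG00000026094) rose by 0.78 and the collagen gene Col6a3 (ENSMUSG00000048126) by 0.87 on the log2 scale, from 35.8 to 65.5 CPM. In these genes, each KO library lay on 1 side of each WT library (6 against 6). An edgeR fit with genotype and surgery as terms called 3845 genes, 1989 higher and 1856 lower in KO. Of these, 457 had no overlap between the genotypes' libraries. The chance of 0.216% for an unselected gene is no measure for them, since they were already called on these libraries. The KO libraries include the KO TAC libraries and KO sham replicate 1, which lay apart from the others. Genotype after sham alone gave 1 call. The Pearson r of the genotype fold changes between the surgeries was 0.590, and 0.106 without KO sham replicate 1. The 3845 calls are therefore not shown to be common to both surgeries. The predicted genes Gm47283 and Gm21887 had adjusted p as small as that of Cd163 (0.000738). Their counts per library were 18 to 401 and 15 to 63 in WT and at most 1 in KO. They have near-identical copies, so their reads are uncertain.

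A knockout line from a substrain with full-length Nnt is argued against: Nnt stood at −0.83 in KO against WT (95% interval −1.26 to −0.40). Of the 456 calls without overlap besides Cd163, 7 lay within 10 Mb of Cd163. Strain DNA carried along with the locus is thus argued against as a main source of these calls in that stretch. Whether calls are enriched there is not decided. The odds ratio of calls without overlap was 1.35 (0.531 to 2.86, Fisher's exact p = 0.374, 7 of 182 genes), an interval that leaves room for an enrichment. The test was run first on all calls, with an odds ratio of 0.817 (0.555 to 1.18, Fisher's exact p = 0.298, 38 of 182), and was then narrowed to calls without overlap. It covers the 10 Mb around Cd163 only. Strain differences elsewhere in the genome stay open, the near absence of Gm47283 and Gm21887 in KO included. What separates the genotypes in these genes, the loss of Cd163 included, was not tested further.

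Clock genes stood in the same direction for TAC against sham in 16 of 16 genes in both genotypes, with a Pearson r of 0.930 and a Spearman rho of 0.921 across genes, which are not independent replicates (permutation p = 1e-05, the smallest that the permutations can give). The 5 genes Arntl, Clock, Npas2, Cry1 and Nfil3 were negative and the 11 others positive in both. No gene of the list passed among all genes. Another hour of collection for TAC than for sham hearts may account for this, and the test would have come out otherwise at a low r. An effect of aortic constriction itself cannot be told apart from it, since the hour is not given in the sources used here and both predict 16 of 16 genes with the same sign.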
